A study of Rattus norvegicus with 20 samples.

How the data were processed

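Total RNA from mammary adenocarcinomas and normal mammary tissue had been extracted with a Maxwell kit, labelled with Cy3 by low-input linear amplification, and hybridised to 1-colour Agilent Whole Rat Genome arrays, 1 sample per array. Per the file headers, each scanner file holds spot and local background brightness in units of intensity, and quality flags (other, 0 or 1). The processed signal is an intensity that the scanner software had corrected for background within the array. The submitters' processing notes name Feature Extraction 10.7.3.1, while the file headers name version 9.5.1.1. The mean spot signal planned for use was not in the files, so the median spot signal and median local background were used. The value table deposited by the authors is on a log2 scale. Its scale was found from the data: it holds the log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 20 arrays, for 20824 probe entries, of which 20793 matched a probe and 31 were controls. The design text names RMA and GeneSpring GX 12, and the value table does not show the quantile step of RMA.

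Analyses were run in R 4.3.3 with limma 3.58.1 and jsonlite 2.0.0, and figures in Python 3.11.15 with matplotlib 3.10.9. The background was corrected by normexp with an offset of 50, and arrays were quantile-normalized on the log2 scale. Of 41012 probes (43379 spots that were not controls, and 1639 control spots), 115 with an outlier mark on some array and 823 that were not well above background on at least 0.5 of the arrays of any group were left out, which left 40074. No spot was saturated (0). For the 3452 genes with several probes the brightest was kept, which gave 36045 genes, where a probe without a gene name stands for a gene. Names came from RefSeq accessions, 10746 of 11186 matched, so 10835 probes had a symbol and 30177 did not, and 8654 tested genes had a symbol. The array's own annotation was not used here, no probe was named Mki67, and genes without a symbol were tested and counted but could not be named. On cancer arrays 61.3% to 79.3% of probes were well above background, and on normal tissue arrays 87.7% to 97.6%.

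Samples were grouped by tissue and obesity group as the labels give them. Cancers were fitted alone for the comparisons among cancers (9 residual degrees of freedom), normal tissues alone for those among normal tissues (5), and all 20 arrays together for cancer against normal and for the interaction (14). Cancer against normal was the mean of the 3 cancer group means minus the mean of the 3 normal group means. Obese against lean was OP minus the mean of the OR and LC group means, since OR rats ate the high-fat diet without the weight gain. Moderated statistics came from limma's empirical Bayes step, p-values were adjusted by Benjamini and Hochberg over all genes, and an adjusted p under 0.05 was the threshold. Adjusted p-values of single genes are limma's throughout. At the median SE, the 95% interval reached 0.257 to either side for OP against OR cancers, 0.433 for OP against OR normal tissue and 0.205 for cancer against normal.

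Gene lists were tested with camera with the correlation estimated from the data, adjusted over the 27 tested lists of each comparison, and also with camera's preset correlation of 0.01 and with fry. Camera ranks a list against all other genes, whereas fry tests whether the genes of a list move one way, not against other genes. The 29 fixed lists were markers of adipocytes, brown fat, luminal epithelium, milk and secretion, myoepithelium, fibroblasts and matrix, endothelium, skeletal muscle, skin keratinocytes, nerve and Schwann cells, macrophages, T and NK cells, B and plasma cells, mast cells and neutrophils, and genes of proliferation, oestrogen and progesterone response, growth factors and receptors, insulin and IGF, cell cycle inhibitors and oncogenes, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, inflammation, MHC class II, interferon response, hypoxia and glycolysis, and immediate early response. B and plasma cells (3 tested members) and neutrophils (4) fell under the minimum of 5 members and were not tested. Members were also adjusted over their list alone. That adjustment corrects neither for the 27 lists nor for the number of comparisons, so some passes can arise by chance. The result of 1 further list and of some single genes is not reported here.

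Named genes, chosen by a rule written before the data were examined, were those with a symbol and an adjusted p under 0.05 with the 10 largest rises and 10 largest falls (5 and 5 within normal tissue and for cancer against normal within an obesity group, and the 10 smallest p for the interaction). Where none passed, the 5 smallest p in each direction were named, and 2 to 4 members with the smallest p in each list. Lep, Adipoq, Esr1, Pgr, Mki67, Erbb2, Igf1 and Csn2 were always named, and are reported for cancer against normal and for obese against lean in both tissues.

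The results were recomputed with 75th-percentile scaling of the processed signal or after normexp, quantile normalization of the processed signal (floor 1), the authors' value table, the mean of a gene's probes, 2 other filters on dim probes, empirical Bayes with trend and robust, a fold of at least 2, slide as a fixed or a random block, a replicate block, a fit on all 20 arrays or array weights by tissue, and leaving out each sample. Scan day as a block, the arrays of 1 scan day, and leaving out slide 4 were added after seeing the data. Other splits of the samples, at most 100 per comparison, were run for comparisons with at least 3 samples in each group.

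The fits were tested on simulated data for 36045 genes with known changes. Noise was drawn independently for each gene and array, with no slide effect and no sample standing apart. The shares below hold for such data only, and fewer changes may be found in the real arrays. At a log2 change of 1, limma recovered 83.6% of changed genes for OP against OR cancers, 64.2% for OP against LC, 71.6% for OR against LC and 85.1% for obese against lean. In normal tissue it recovered 35.8% for OP against OR, 37.3% for OP against LC, 35.8% for OR against LC and 55.2% for obese against lean, and 86.6% for cancer against normal. For cancer against normal 51 unchanged genes were called, and 6.38% of unchanged genes had an unadjusted p under 0.05. The simulated spreads of the 2 tissues differed, and array weights by tissue were tried for this reason. Whether the spreads cause the excess was not tested.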

Results

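Gene expression was measured in mammary cancers and normal mammary tissue of female Sprague-Dawley rats that had been exposed to gamma rays. Rats whose food drew 45 kcal% from fat had been divided by body weight into obesity-prone (OP) and obesity-resistant (OR) animals, and lean controls (LC) ate a standard diet with 10 kcal%. All were irradiated at 7 weeks of age with 4 Gy and followed for 30 weeks. The 20 arrays held 12 adenocarcinomas (6 OP, 3 OR and 3 LC) and 8 normal tissues (3 OP, 2 OR and 3 LC), 1 array per sample, on 5 slides read on 2 scan days. Slides 1, 2 and 3 held both tissues, slide 4 held 4 OP cancers, and slide 5 held 2 OR and 2 LC cancers. The labels and the design text give the number of tissues, and do not say for every sample that it came from a separate animal, so the p-values measure the spread between these samples.

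The arrays of the 2 tissues differed in how many probes gave a signal. In the cancers 68.5% ± 6.60 (SD, n = 12) of the probes were well above background, against 94.1% ± 3.32 (n = 8) in normal tissue, with no overlap (61.3% to 79.3% against 87.7% to 97.6%). The median probe minus the 75th percentile of its array was -3.08 ± 0.13 (log2) in cancers and -1.60 ± 0.36 in normal tissue. The negative control spots had close log2 signals before background correction (5.70 in cancers and 5.80 in normal tissue). In the processed signal, 5406 probes that were not well above background on any cancer array had a median log2 signal of 2.15 in cancers and 4.82 in normal tissue. These probes were picked for being dim in cancers, so part of this gap is fixed by the choice. Among the cancers, the share well above background was 65.6% ± 7.10 in OP, 74.8% ± 3.51 in OR and 68.1% ± 4.09 in LC. The first principal component, with 55.7% of the variance, separated cancers from normal tissue.

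**Figure D1:**
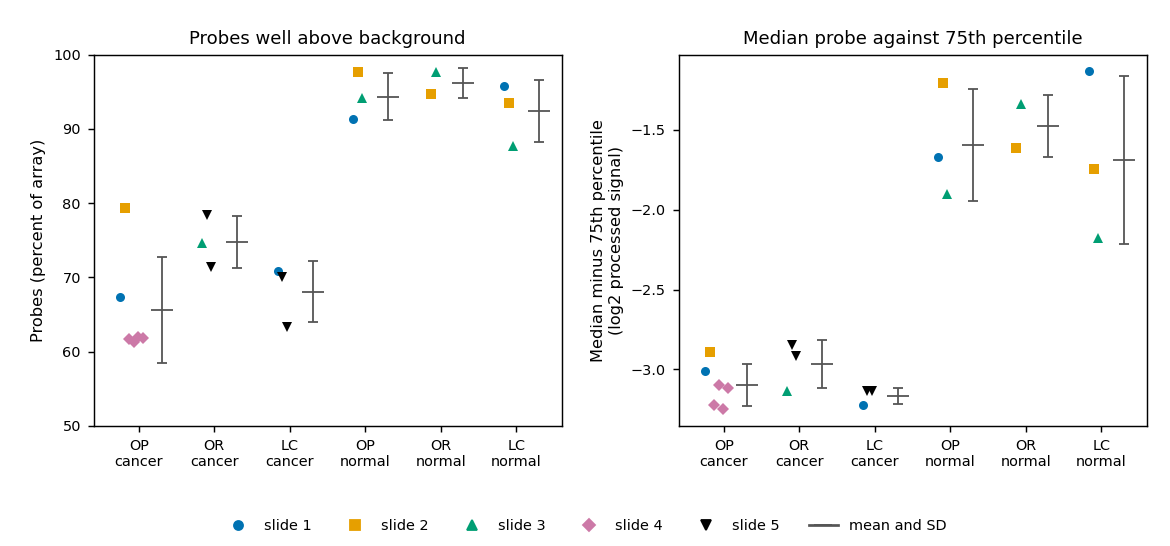
Share of probes well above background (left, percent) and the array's median log2 signal minus its 75th percentile (right, log2) for each array, by tissue and obesity group, with bars for the group mean and SD and colours and shapes for the slide. Cancer arrays lie between 61.3% and 79.3%, and normal tissue arrays between 87.7% and 97.6%.

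Cancers were compared with normal tissue to find what distinguishes the tumours. Among genes with the largest rise were Mmp3, a matrix-degrading protease (log2 difference 5.19, SE 0.611), Bst2, an interferon-inducible membrane protein (4.28, SE 0.409), Cdkn2a, which encodes a cyclin-dependent kinase inhibitor (3.29, SE 0.482), Cldn7, a tight junction protein (3.18), Areg, a ligand of the EGF receptor (3.14), and Slc16a3, a lactate transporter (8.55-fold). Padi3, a protein-arginine deiminase (4.03), Tmem54 (3.85), Gp2 (3.76) and Prom2 (8.56-fold, SE 0.187 on the log2 scale) completed the 10. The largest falls were in products of fat cells: adiponectin (Adipoq, -8.26, SE 0.144), resistin (Retn, -8.04, SE 0.116), the fatty acid binding protein Fabp4 (-7.38, SE 0.230) and the glycerol channel Aqp7, which was not well above background on any cancer array and was at least 44.3-fold lower there. Ces1d, a carboxylesterase (-8.24), Grifin (-6.85), Slc7a10, an amino acid transporter (-6.44), Car3, a carbonic anhydrase (-5.62), Cpa1 (-5.60) and Ccl21, a lymphocyte-attracting chemokine (-5.52, SE 0.605), made up the rest.

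In limma, 22507 of 36045 genes passed an adjusted p of 0.05, 10439 higher and 12068 lower in cancers (46.4% higher), and 4185 of them also changed at least 2-fold, 2069 up and 2116 down. The adjusted p was 2.66e-06 for Mmp3, 3.16e-07 for Bst2, 2.28e-05 for Cdkn2a, 3.01e-05 for Areg, 4.34e-16 for Adipoq, 5.63e-17 for Retn, 7.45e-13 for Fabp4 and 5.07e-14 for Aqp7. The log2 level was 13.1 ± 1.81 (mean of the group means, SD over 12 cancers) against 7.86 ± 0.613 (n = 8) for Mmp3, and 6.98 ± 0.22 against 15.24 ± 0.48 for Adipoq. Apart from Areg, none of the 20 overlapped between the cancers and the normal tissues, which chance gives for 0.00159% of genes taken at random, but these were picked for their difference. Within slides 1, 2 and 3 Mmp3 differed by 6.14, 2.52 and 6.98 and Adipoq by -8.74, -8.30 and -7.86. With slide as a block Mmp3 stood at 5.57, Bst2 at 3.65, Cdkn2a at 2.19, Adipoq at -8.36 and Retn at -8.18. These slides held 2, 1 and 1 cancers, and the other slides held no normal tissue. Here and below, within-slide and block values therefore set only 4 cancers directly against normal tissue. An at-least fold set the brighter group against, on each dimmer array, the higher of the gene's own signal and the lowest signal among probes well above background. Ces1d was well above background on 4 of the 12 cancer arrays, Cpa1 on 3, Grifin and Car3 on 9 each, and Adipoq and Fabp4 on 11 each, so their falls rest partly on signals near background.

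The direction of all genes together depended on the scaling. Quantile normalization, used throughout, gives every array the same distribution. Scaling the processed signal to the 75th percentile instead moved the median of all genes by -1.51 and left 17.7% of 29137 calls higher in cancers, and after normexp the same scaling moved it by -0.80, with 17.3% of 29359 calls higher. In the authors' deposited value table the median was -0.19 and 39.4% of 12456 calls were higher. Differences are therefore relative to the quantile scale, and families whose direction turned under another scaling are named with their result.

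Of the genes chosen in advance, Erbb2, the receptor tyrosine kinase HER2, rose by 1.80 (SE 0.145, adjusted p = 5.54e-08, 1.52 with slide as a block), and the progesterone receptor Pgr by 1.71 (SE 0.243, adjusted p = 1.70e-05, block value 1.53). The growth factor Igf1 fell by 3.16 on the log2 scale (SE 0.364, adjusted p = 2.17e-06, block value -3.37). Leptin (Lep) had a difference of -0.62 (SE 0.0757, adjusted p = 3.83e-06, block value -0.68), with 1 of 12 cancers well above background. The oestrogen receptor Esr1 was 0.35 higher (SE 0.0836, adjusted p = 0.00189, block value 0.36), near background in both tissues, and -1.41 and -0.62 under the 75th-percentile scalings. The beta-casein gene Csn2, a milk protein, varied between samples (1.53, SE 1.69, adjusted p = 0.448), and passed only with slide as a block (5.31, adjusted p = 0.0358, with 0.53 to 5.31 over all alternatives).

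Fat cell genes fell together. All 19 tested adipocyte markers fell, also when adjusted over the list alone, with a median log2 difference of -3.36 (Pck1, the key enzyme of glyceroneogenesis, -4.98, adjusted p = 2.57e-13). The list's camera test gave adjusted p = 0.129 with an estimated correlation and 3.93e-15 with the preset correlation of 0.01. Its median was -2.53 with slide as a block, and -3.33, -2.90 and -2.16 within slides 1, 2 and 3. Of the fatty acid oxidation list 14 of 22 fell and 4 rose (median -0.53, camera 0.763, block -0.32), among them Cpt1b, the carnitine palmitoyltransferase of muscle and fat (-1.90, adjusted p = 3.53e-06). In fatty acid synthesis 4 of 13 fell and 3 rose, or 2 rose when adjusted over the list alone. The desaturase Scd (-5.50, adjusted p = 3.09e-07) and Thrsp (-4.39, adjusted p = 1.71e-06) fell; the list's median was 0.07 while its mean was -0.80 (camera 0.976, block median 0.10), and the median was -0.60 under 75th-percentile scaling. Of 21 cholesterol synthesis genes 11 rose and 4 fell (median 0.33, camera 0.785, block 0.31), with Insig1, which holds back sterol synthesis, at -2.27 (adjusted p = 1.21e-07) and Nsdhl at 0.97 (adjusted p = 3.86e-07, but 0.18 and 0.150 with 75th-percentile scaling after normexp). Of the 5 brown fat genes 2 rose and 1 fell (median 0.32, camera 0.763, block 0.45), and the median turned to -1.50 under 75th-percentile scaling, as did Dio2, an activator of thyroid hormone (0.53, adjusted p = 1.08e-05, against -0.59 and -0.48 under the 75th-percentile scalings).

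Luminal epithelial genes rose. Of 14 tested, 13 rose (median 1.39), including the keratins Krt8 (2.33, adjusted p = 1.05e-06) and Krt18 (1.68, adjusted p = 2.24e-06), the adhesion molecule Epcam (2.49, adjusted p = 3.66e-06) and the transcription factor Gata3 (1.37). The list had adjusted p = 0.763 with an estimated correlation and 1.86e-05 with the preset one, a block median of 1.63, and 2.12, 0.52 and 1.72 within slides 1, 2 and 3. Basal and myoepithelial genes went both ways: 3 of 9 rose and 4 fell (median 0.42 and -0.05 with slide as a block, camera 0.976), with the basal keratin Krt5 at 2.41 (adjusted p = 5.89e-05) and the oxytocin receptor Oxtr at -1.73 (adjusted p = 2.33e-06). Camera's direction was up and that of fry, a rotation test of the list against no change, was down (adjusted p = 0.895). Of 11 milk and secretory genes 1 rose and 2 fell (median -0.29, and 1.01 with slide as a block, camera 0.976): the lipase Cel (0.99, adjusted p = 0.00362, lost under both 75th-percentile scalings and in the authors' table), Csn1s2b (-0.29, adjusted p = 0.00505, 3 of 12 cancers above background) and Xdh, a protein of the milk fat globule (-1.37, adjusted p = 0.00776). Skin keratinocyte markers were mixed, with 2 of 5 up and 1 down (median -0.02, mean 0.18, camera 0.976, block -0.10). Krt4 was at -0.96 (adjusted p = 5.74e-05, 5 of 12 cancers above background) and Krt15 at 1.60 (adjusted p = 0.00117), and Krt15 was lost with slide as a block (1.24, adjusted p = 0.0515) and on scan day 2 alone (1.13, adjusted p = 0.123).

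Genes of cell division rose together. All 15 tested proliferation genes rose (median 1.64, block 1.65, and 1.80, 1.93 and 1.43 within slides 1, 2 and 3), among them the mitotic kinases Plk1 (2.96, adjusted p = 5.21e-06) and Aurka (1.59, adjusted p = 5.05e-06), Ccnb2, a mitotic cyclin (2.14), and Rrm1, a subunit of ribonucleotide reductase (1.64, adjusted p = 1.99e-06). The list's adjusted p was 0.763 with an estimated correlation and 6.75e-06 with the preset one. Of 11 cell cycle inhibitors and oncogenes 5 rose and 2 fell (median 0.38, camera 0.763, block 0.26, -0.08 under 75th-percentile scaling), with Mycn at 1.67 (adjusted p = 1.02e-06). Of 14 immediate early genes 5 rose and 1 fell, or 0 fell when adjusted over the list alone (median 0.41, camera 0.763, block 0.29). Ier2 was at 1.60 (adjusted p = 9.19e-06), and Zfp36, which destabilises mRNA, was at 0.52 (adjusted p = 0.000162) but at -0.59 and -0.45 under the 75th-percentile scalings.

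Growth factor and hormone lists were mixed. Of 13 growth factor receptors and ligands 6 rose and 3 fell (median 0.40, camera 0.763, block 0.02, -0.21 under 75th-percentile scaling), with Tgfa, an EGF receptor ligand, at 2.06 (adjusted p = 2.27e-07) and Hbegf at 1.14. Of 13 oestrogen and progesterone response genes 7 rose and 3 fell (median 0.35, camera 0.763, block 0.36, -0.69 under 75th-percentile scaling), among them Wnt4, a paracrine signal of progesterone (2.23, adjusted p = 1.24e-06), Cited1 (2.51, adjusted p = 5.31e-06) and the calcitonin receptor Calcr (-0.92). Of 14 insulin and IGF genes 7 rose and 5 fell, with a median of 0.35 against a mean of -0.18 and fry's direction down (camera 0.976, block median 0.31, -0.43 under 75th-percentile scaling). Igfbp6, an IGF-binding protein (-3.31, adjusted p = 1.08e-07), the regulatory PI3-kinase subunit Pik3r1 (-0.90, adjusted p = 1.88e-06) and the insulin receptor substrate Irs1 (-1.42) fell. Of 15 hypoxia and glycolysis genes 9 rose and 2 fell (median 0.75, camera 0.763, block 0.88, and 0.70, 0.97 and 1.23 within slides 1, 2 and 3), including the glycolytic enzymes Eno1 (1.54, adjusted p = 2.26e-06) and Aldoa (1.90, adjusted p = 3.67e-06).

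Genes of connective tissue and vessels fell. Of 12 fibroblast and matrix genes 10 fell and 0 rose (median -1.43, block -1.83, camera 0.763 with an estimated correlation and 0.0732 with the preset one), including fibrillin Fbn1 (-2.40, adjusted p = 4.13e-05), Sparc (-1.71, adjusted p = 0.000102) and decorin Dcn (-1.98). Within slides 1, 2 and 3 the median was -2.54, -0.95 and -1.05. Of 6 endothelial genes 5 fell and 1 rose (median -0.95, camera 0.763, block -1.13), with Esam at -1.66 (adjusted p = 1.37e-05) and Kdr, a VEGF receptor, at -1.72 (adjusted p = 2.21e-05). Of 10 nerve and Schwann cell genes 5 fell and 1 rose (median -0.43, camera 0.763, block -0.33), with the myelin protein Pmp22 at -2.39 (adjusted p = 1.12e-07). Of 12 skeletal muscle genes 1, Tnnt3, fell (-1.10, adjusted p = 0.0396) and 0 rose, and 0 passed when adjusted over the list alone (median -0.27, camera 0.976, block -0.07). The Tnnt3 call was fragile: it ended with slide as a block (-1.07, adjusted p = 0.224), with scan day as a block (0.147), on scan day 2 alone (0.0938) and with array weights by tissue (0.0642). It also ended without any 1 of 15 samples (adjusted p from 0.0504 to 0.160), namely OP cancers 1, 3, 4 and 5, all OR cancers, LC cancers 1 and 2, all OP normal tissues, OR normal replicate 2 and LC normal replicates 1 and 3.

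Immune lists moved in both directions. Of 11 macrophage genes 4 fell and 0 rose (median -0.31, block -0.60, camera 0.976), with Cd14 at -1.47 (adjusted p = 0.00399) and Tyrobp at -1.02 (adjusted p = 0.00718), the last lost with slide as a block (-1.09, adjusted p = 0.0654) and with scan day as a block (-0.93, adjusted p = 0.0637). Of 15 T and NK cell genes 1 rose and 1 fell, or 1 and 0 when adjusted over the list alone (median -0.34, block -0.39, camera 0.976). The list mean of LC normal replicate 3 was 10.83, against 7.71 to 8.25 in the other normal tissues, so the level of normal tissue leans on it. Gzmb, a granzyme, was at 0.74 (adjusted p = 0.00571) but at -0.19 and -0.16 under the 75th-percentile scalings, and the pore-forming Prf1 at -1.02 (adjusted p = 0.0270) was lost with slide as a block (-1.21, adjusted p = 0.0828), on scan day 2 alone (0.145), and without OR cancer replicate 1, LC cancer replicate 3 or OR normal replicate 2. Gzmb was lost with scan day as a block (0.43, adjusted p = 0.174). Of 16 interferon response genes 5 rose and 1 fell, or 4 and 1 when adjusted over the list alone (median 0.33, block 0.26, camera 0.976), with Mx2 at 1.76 (adjusted p = 0.000417) and Ifit3 at -0.66 (adjusted p = 0.000291). Of 15 inflammation genes 5 rose and 2 fell (median 0.26, block 0.01, camera 0.976, -0.29 under 75th-percentile scaling), with osteopontin Spp1 at 3.05 (adjusted p = 4.17e-05) and Ptgs2, not well above background on any cancer array, lower (adjusted p = 3.94e-05). Of 8 MHC class II genes RT1-DOb fell (-0.48, adjusted p = 0.0259) and 0 rose. It was lost with slide or scan day as a block (adjusted p = 0.182 and 0.108), on scan day 2 alone, with a replicate block, and without OR cancer replicate 3, OP normal replicate 2 or OR normal replicate 2. RT1-DMa (0.67, adjusted p = 0.0720) passed upward under both 75th-percentile scalings (0.81 and 0.88), in the authors' table (0.83), and without OP cancer replicates 2 or 6 or OR cancer replicate 3. Of 8 mast cell genes Tpsab1 fell (-0.51, adjusted p = 0.0329). Tpsab1 was lost under both 75th-percentile scalings, in the authors' table (-0.33, adjusted p = 0.156), with a replicate block (0.128), scan day as a block (0.118) and array weights (0.0536), and without OR cancer replicates 1 or 3, LC cancer replicates 1 or 2, OP normal replicate 2, OR normal replicate 1 or LC normal replicate 1 (0.0521 to 0.0874). Neither RT1-DOb nor Tpsab1 passed when adjusted over the list alone, and the medians were -0.17 (mean 0.10, block -0.24, camera 0.983) and -0.30 (block -0.72, camera 0.976).

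**Figure D2:**
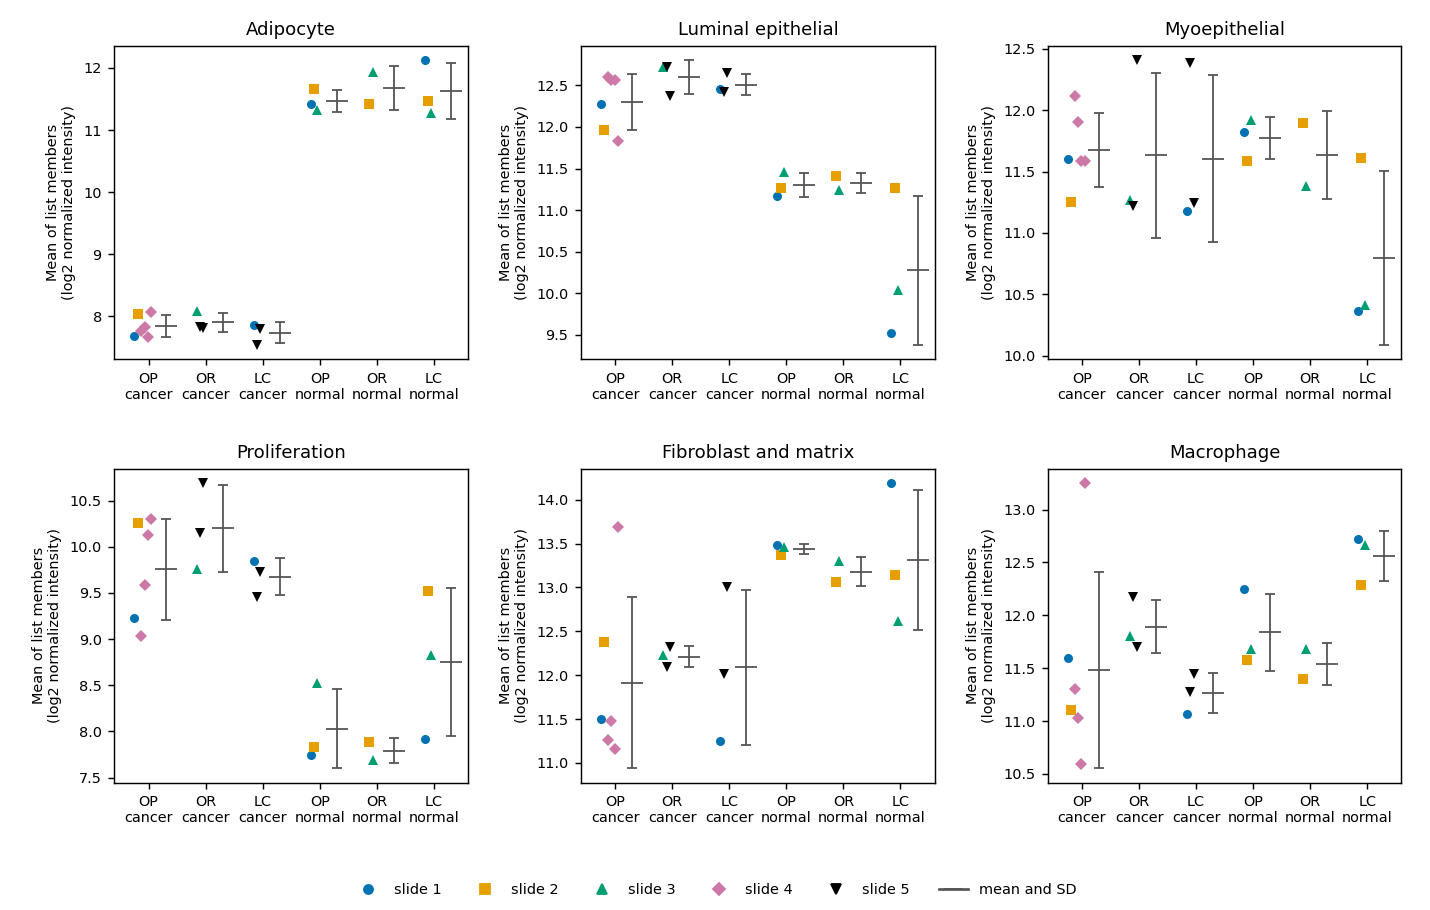
Mean log2 level of the tested genes of 6 lists (adipocyte, luminal epithelial, myoepithelial, proliferation, fibroblast and matrix, macrophage) in each array, by tissue and obesity group, with bars for the group mean and SD and colours and shapes for the slide. The adipocyte mean is 7.84 ± 0.17 in OP cancers and 11.46 ± 0.18 in OP normal tissue, and the luminal mean of LC normal tissue (10.28 ± 0.90) lies under those of OP (11.30 ± 0.15) and OR (11.33 ± 0.12) normal tissue.

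Camera with the preset correlation called 3 of the 27 lists in this comparison, fry 15, and camera with an estimated correlation 0. The 3 lists called with the preset correlation were adipocyte, luminal and proliferation. Several markers are not exclusive to the cell type of their list, since lipid synthesis genes are also used by mammary epithelium.

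The difference between cancer and normal tissue was also taken within each obesity group. In OP rats the largest rises were in Padi3 (4.30, adjusted p = 0.000250), Gp2 (4.23), Mmp3 (4.18, SE 0.917, adjusted p = 0.00187), Bst2 (3.55, and 1.72 with slide as a block) and Cdkn2a (3.35, adjusted p = 0.00168, lost with slide as a block at 2.36, adjusted p = 0.0554). The largest falls there were in Ces1d (-8.08), Adipoq (-7.98, SE 0.216), Retn (-7.57), Fabp4 (-7.10) and Grifin (-6.40). In OR rats they were Mmp3 (5.49, SE 1.18, adjusted p = 0.00313), Bst2 (5.13), Spp1 (4.34), Padi3 (4.14, lost with slide as a block at 3.09, adjusted p = 0.0747) and Plk1 (4.13). In the other direction they were Ces1d (-8.23), Adipoq (-8.13), Retn (-7.86), Slc7a10 (-7.24) and Fabp4 (-7.13). In LC rats Mmp3 (5.91, SE 1.06, adjusted p = 0.000474), Areg (4.86), Tmem54 (4.32), Bst2 (4.16) and Cldn7 (4.04) rose most. There Retn (-8.68), Adipoq (-8.65), Fabp4 (-7.89) and Grifin (-7.07) fell most, with Ces1d at least 322-fold lower.

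All 19 adipocyte genes fell in each of the 3 obesity groups. Their median was -3.42 in OP (adjusted p = 0.0588 with an estimated correlation), -3.70 in OR (0.0308) and -3.23 in LC (0.0726). The OR value was the 1 list call made with an estimated correlation in any comparison, and it ended with slide as a block (-2.42, adjusted p = 0.214). All 15 proliferation genes rose in OP (median 1.55) and in OR (2.30), and 7 rose in LC (0.90), while 8 of 14 luminal genes rose in OP (0.88), 7 in OR (1.02, or 9 when adjusted over the list alone) and 13 in LC (2.40, or 14 over the list alone). The luminal means of the cancers were 12.30 in OP, 12.60 in OR and 12.51 in LC, and LC normal replicates 1 and 3 (9.52 and 10.04) stood below the other normal tissues. The proliferation means of the cancers were 9.76, 10.20 and 9.67, and LC normal replicates 2 and 3 (9.52 and 8.82) stood above the other normal tissues (7.69 to 8.52). These lists had estimated-correlation adjusted p between 0.582 and 0.793, and the differences between the groups in their size were tested only gene by gene. Of 12 fibroblast and matrix genes 7 fell in OP (median -1.68, 8 over the list alone), 1 in OR (-1.29) and 4 in LC (-1.25).

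In limma 16062 genes passed in OP (7633 higher), 10245 in OR (5022 higher) and 15701 in LC (7176 higher), and of these 3527, 4121 and 5068 changed at least 2-fold. Without OR normal replicate 2 the OR count was 3587, and without replicate 1 it was 6333, each leaving 1 normal sample that was assumed to vary like the others. Under 75th-percentile scaling of the processed signal the calls higher in cancers made up 13.2% in OP, 11.2% in OR and 14.8% in LC, against 47.5%, 49.0% and 45.7% with quantile normalization. The median of all genes moved there by -1.43, -1.56 and -1.52.

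Whether the cancer difference varied with obesity was tested by a moderated F-test of the interaction, in which limma called 0 genes. At an unadjusted p under 0.05 it had 2534 (7.03%), where chance gives 1802. In the simulated data the same test gave 7.21% of unchanged genes such a p, so no excess is shown. The 10 smallest p-values belonged to Zcchc9, a zinc finger protein, and Gtf2ird1 (adjusted p = 0.105 each), Magi3, Nudt1, an enzyme that clears oxidised nucleotides, and Blvra, biliverdin reductase (0.138 each), Reep2, Or4f61d, Mmd, Irf2bpl and Tubb3 (up to 0.189). Zcchc9 stood at 11.28 ± 0.26 in OP cancers, 10.61 ± 0.09 in OR and 10.35 ± 0.03 in LC, and at 11.72 ± 0.14, 12.11 ± 0.01 and 11.78 ± 0.14 in the normal tissues. The count was 6 with slide as a block, 494 without LC normal replicate 1, 22 without LC normal replicate 2, 8 without OR normal replicate 2, and 5 without OP normal replicate 1. Zcchc9 passed without LC normal replicate 1 (adjusted p = 0.0217) and without OP cancer replicate 6 (0.00325), with 0.00325 to 0.999 over its alternatives.

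Obesity-prone and obesity-resistant cancers came from the same diet and differed in weight gain. The largest differences toward OP by p were in Slc38a4, an amino acid transporter (1.02, SE 0.157), Mras, a Ras-family GTPase (0.93, SE 0.171), the receptor kinase Grk4 (0.70), Zcchc9 (0.67) and Tram1, a translocon-associated protein (0.44). Toward OR they were in Svs5 (-0.38, 1 of 6 OP cancers above background), Bcas1 (-0.55), the coagulation factor F13a1 (-0.69, 2 of 6 OP), Tgfa (-0.68, SE 0.132) and the keratin Krt33a (-0.70). Slc38a4 was at 8.48 ± 0.27 (n = 6) in OP, 7.46 ± 0.24 (n = 3) in OR and 7.62 ± 0.08 (n = 3) in LC. None passed: each had adjusted p = 0.363, and limma called 0 genes, with 3926 at an unadjusted p under 0.05 against 1802 by chance. With slide as a block, which ties OP to OR only through the LC cancers, since OP and OR shared no slide, limma called 4 genes, of which Or2v1 (2.31, adjusted p = 0.0177), chosen after its values were seen, had a symbol, and Slc38a4 was at 1.52, Mras at 1.62, Grk4 at 0.82, Zcchc9 at 0.61, Tram1 at 0.65, Tgfa at -1.19 and Krt33a at -0.59. F13a1 (-0.38), Bcas1 (-0.33) and Svs5 (-0.24) shrank there. All these block values rest on 1 OP cancer, the one on slide 1.

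The hypoxia and glycolysis list had a median of -0.75 and the proliferation list of -0.41 between OP and OR cancers, with adjusted p = 0.000157 and 0.00457 with the preset correlation and 0.919 for both with an estimated correlation. MHC class II (-0.99), luminal (-0.34), skin (-0.36), cholesterol synthesis (-0.11) and skeletal muscle genes (0.73) were also called with the preset correlation alone. The skin list mean was 10.27 in OR cancer replicate 3 and 8.52 and 8.78 in OR replicates 1 and 2, against 8.54 to 8.91 in OP. The skeletal muscle mean was 10.72 in OP cancer replicate 6 and 9.29 in replicate 2, and 7.40 to 7.48 in the other OP cancers, near the 7.45 to 7.55 of OR. In each list 0 genes passed over all genes. Adjusted over the list alone, the adhesion molecule Cdh1 (-0.47, adjusted p = 0.0158), Tgfa (0.00389), Ivl (-0.36, 0.0307) and Gfap (-0.47, 0.0269) passed. Other calls of single genes came with 75th-percentile scaling (12, all lower in OP, median of all genes -0.15), quantile normalization of the processed signal (2), without OP cancer replicate 6 (45, of which 41 higher in OP), where Slc38a4 and Zcchc9 passed, and without the 4 OP cancers of slide 4 (1169).

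Obesity-prone and lean control cancers differed in both diet and weight. The smallest p toward OP belonged to Zcchc9 (0.93, SE 0.133), Ptpn11, the tyrosine phosphatase SHP2 (0.68), the transcription elongation factor Eloa (0.95), Pdap1 (0.85) and the translation termination factor Gspt1 (0.80, with its other probe of opposite sign). Toward LC they belonged to Tdrd7 (-0.56), Ubl7 (-0.85), the translation elongation factor Eef1a1 (-0.64), Cops8 (-0.31) and Klre1, an NK cell receptor not well above background on any OP cancer array and at least 1.27-fold higher in LC. None passed, with adjusted p from 0.193 to 0.225; limma called 0 genes, and 2599 had an unadjusted p under 0.05. With slide as a block, an estimate that rests on slide 1, the only one with both groups (1 cancer each), limma called 26 genes, and Zcchc9 was at 0.93, Ptpn11 at 1.09 and Ubl7 at -0.97. The count was 214 without OP cancer replicate 6 (205 higher in OP), 1778 without the 4 OP cancers of slide 4, and 3 without LC cancer replicate 1. In a fit on all 20 arrays it was 2, among them Zcchc9 (adjusted p = 0.0399, with 0.000839 to 1 over its alternatives).

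Interferon response genes were lower in OP than in LC cancers in the median (-0.65, and -1.86 on slide 1), with adjusted p = 1.04e-05 with the preset correlation and 0.929 with an estimated correlation. The LC cancer of slide 1, replicate 1, stood highest of all cancers in this list (mean 10.38, against 9.58 and 8.81 in LC replicates 2 and 3), so both medians lean on it. Inflammation (0.38) and cholesterol synthesis genes (0.17) were called with the preset correlation (0.0285 and 0.0424) and not with an estimated correlation (adjusted p = 0.975 each). The inflammation mean was highest in OP cancer replicate 6 (10.17, against 8.56 to 9.21 in the other OP cancers). In all lists 0 genes passed over all genes, and adjusted over the list alone Cdh1 (-0.45, 0.0218), Tgfa (-0.51, 0.0322) and the DNA repair gene Brca2 (0.48, 0.0200) did.

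Between obesity-resistant and lean control cancers, which differed in diet and less in weight, Gdf10, a TGF-beta family member, had the largest difference among the named genes (-2.41, SE 0.538), followed by Syt8, a synaptotagmin (1.68). Elastin (Eln, -0.85), Nrxn2 (-0.88, its other probe of opposite sign), Camk2b (-0.75) and Nrxn3, at least 1.57-fold higher in LC and above background on 0 of 3 OR arrays, were also lower. Bcas1 (0.63), F13a1 (0.71), Slc25a18 (0.35, and -0.03 under 75th-percentile scaling after normexp) and Tsc1 (0.24) were higher. All had adjusted p = 0.998 and limma called 0 genes; 1510 had an unadjusted p under 0.05, fewer than the 1802 of chance. On slide 5, with 2 cancers of each group, Syt8 differed by 1.93 and Gdf10 by -3.19, in samples from which the genes were picked. The value of Gdf10 was the same with slide as a block, where limma called 1 gene, without a symbol here. Cholesterol synthesis (0.27, adjusted p = 2.40e-07), proliferation (0.53, 8.16e-05), hypoxia (0.36, 0.00793) and interferon genes (-0.44, 0.00793) were among 9 lists called with the preset correlation, and these 4 each had adjusted p = 0.634 with an estimated correlation. On slide 5 their medians were 0.46, 0.86, 0.69 and 0.04. Adjusted over the list alone, Retn (0.59, 0.0393), Cebpa (0.47, 0.0393) and Dio2 (-0.54, 0.0163) passed. With 27 lists each adjusted alone, such passes can arise by chance. Dio2 was dim (6.74 in OR and 7.28 in LC), and well above background on 2 of 3 OR arrays.

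Obese was also set against lean among the cancers, as OP minus the mean of the OR and LC group means. Zcchc9 was at 11.28 ± 0.26 (n = 6) in OP and 10.48 ± 0.15 (n = 6) in the others, a difference of 0.80 (SE 0.109, 0.77 with slide as a block). Slc38a4 (0.94, SE 0.128, block 1.44), Mras (0.86, block 1.43), Ptpn11 (0.54, block 0.96) and the transcription factor Mef2a (0.55, block 0.87) were the other 4 with the smallest p toward OP. Tdrd7 (-0.52, block -0.50), Ubl7 (-0.76, block -0.81), Eef1a1 (-0.59, block -0.63), the protein disulphide isomerase Pdia4 (-0.55, block -0.40) and Tgfa (-0.60, SE 0.108, block -1.10) lay lower. The block value of Tgfa leans on OP cancer replicate 1, the OP cancer of slide 1, which stood apart from the other OP cancers (9.78 against 10.34 to 10.39). The 2 groups of 6 did not overlap for any of these 10, which chance gives for 0.216% of genes each, but the genes were picked by p. None passed, with adjusted p from 0.120 to 0.126, and limma called 0 genes, with 4099 at an unadjusted p under 0.05 against 1802. The median width of the 95% interval was ± 0.21.

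**Figure D3:**
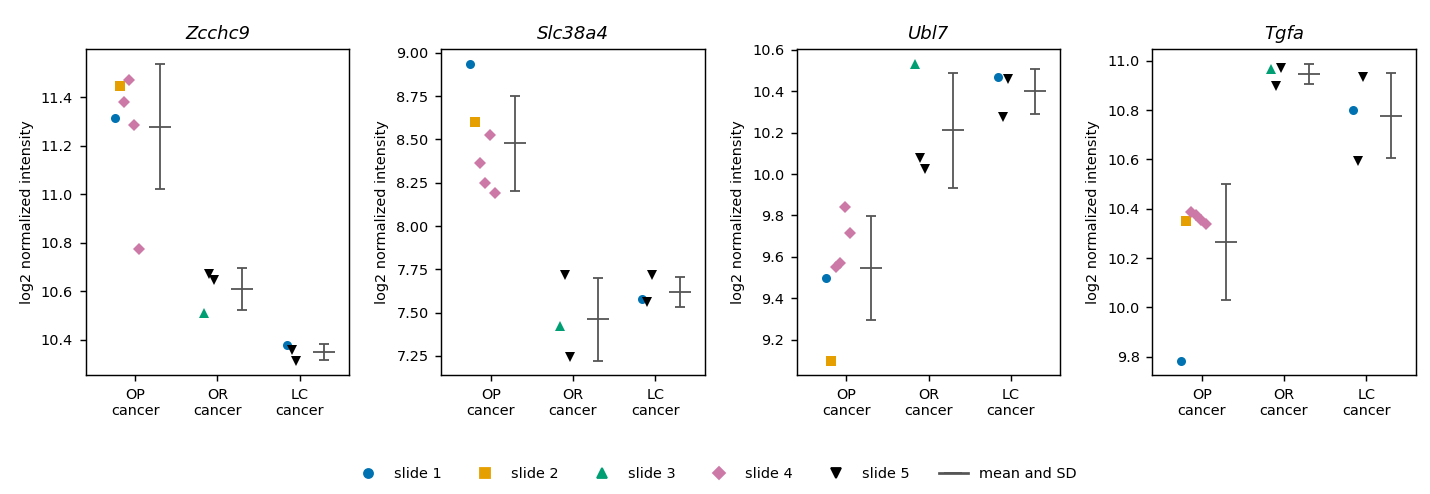
Log2 level of Zcchc9, Slc38a4, Ubl7 and Tgfa in each cancer of the OP, OR and LC groups, with bars for the group mean and SD and colours and shapes for the slide. Zcchc9 averages 11.28 ± 0.26 in OP cancers, 10.61 ± 0.09 in OR and 10.35 ± 0.03 in LC, and 1 OP cancer, replicate 1, lies apart from the others in Tgfa.

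Without OP cancer replicate 6, 516 genes passed (454 higher in OP), among them all 10 named above, and without LC cancer replicate 1 the count was 1. Without the 4 OP cancers of slide 4 it was 2313, with slide as a block 12, and in a fit on all 20 arrays 2, among them Zcchc9 (adjusted p = 0.0202, with 0.000498 to 1 over its alternatives). Of the genes chosen in advance, Erbb2 was at -0.55 (SE 0.176, adjusted p = 0.299, with -1.02 and 0.0158 without slide 4 and 0.0158 to 1 over its alternatives), Igf1 at -0.46 (1.37 with slide as a block), Csn2 at 0.91 (SE 2.16, -7.08 with slide as a block), and Adipoq at -0.06, Esr1 at 0.03, Pgr at -0.05 and Lep at -0.00859 differed by less than their SE. Igf1 and Csn2 also turned on scan day 2 alone and without slide 4, and Pgr (0.81) and Lep (0.0288) turned with slide as a block. The block values here too rest on OP cancer replicate 1 alone among the OP cancers. Interferon (-0.47) and hypoxia genes (-0.46) each had adjusted p = 0.00192 with the preset correlation, luminal (-0.24) 0.0114 and skeletal muscle genes (0.75) 0.0140, and all 4 had adjusted p = 0.981 with an estimated correlation. Skeletal muscle, macrophage (13.25) and fibroblast (13.69) list means were highest of all cancers in OP cancer replicate 6. Adjusted over the list alone, Cdh1 (-0.46, adjusted p = 0.00392, block value -0.18), Epcam (-0.56, 0.0369, block value -0.14), Tgfa (0.00217) and Brca2 (0.37, 0.0296, block value 0.54) passed, and over all genes 0 did.

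In normal mammary tissue, OP against OR gave the fewest genes with a small p. The decoy receptor Tnfrsf11b (1.11), the endothelial adhesion molecule Sele (0.97), Haus4 (0.47), Pdia3 (0.41) and Gnb2 (0.39) had the smallest p toward OP, and Gata3 (-0.82), Kcns1 (-0.57), Ins1 (-0.42), Zcchc9 (-0.39) and Cep63 (-0.29) toward OR. All had adjusted p = 1; limma called 0 genes and 221 had an unadjusted p under 0.05, fewer than the 1802 of chance. On slides 2 and 3, which held 1 sample of each group, Tnfrsf11b differed by 0.68 and 0.99 and Gata3 by -0.51 and -0.66. These are samples from which the genes were picked. Skeletal muscle genes had a median of -0.70 (0.05 on slide 2 and -1.54 on slide 3) and adipocyte genes of -0.24 (0.26 and -0.66), 2 of 9 lists called with the preset correlation (4.70e-07 and 0.00240), with adjusted p = 0.539 and 0.756 with an estimated correlation. In all lists 0 genes passed, over all genes or over the list alone.

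OP normal tissue had higher levels than LC normal tissue of Egr1, an immediate early transcription factor (1.28, SE 0.129), Trib1, a pseudokinase (1.66, SE 0.188), Irf2bpl (1.08), Magi3 (1.12) and podocalyxin Podxl (1.69). It had lower levels of Rarres1 (-0.74, SE 0.0706), Blvra (-0.84), calmodulin Calm3 (-0.75), the chemokine Ccl24 (-1.14) and Sfxn1 (-0.63). None passed (adjusted p from 0.156 to 0.179). limma called 0 genes and 3177 had an unadjusted p under 0.05. On slides 1, 2 and 3, with 1 sample of each group, Egr1 differed by 1.07, 1.48 and 1.29 and Rarres1 by -0.81, -0.66 and -0.76, the same samples from which the genes were picked. The count was 657 without LC normal replicate 1 (469 higher in OP), 25 without LC normal replicate 2, 1 without LC normal replicate 3, 1 without OP normal replicate 1 (Qprt at -1.86, chosen after its values were seen) and 193 in a fit on all 20 arrays.

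OR normal tissue set against LC gave Gata3 (2.07, SE 0.280, block 1.99), Tacr1, the substance P receptor (1.60), the neurotrophin receptor Ntrk3 (1.59), Trib1 (1.56) and Or2n1 (0.96) as the genes with the smallest p toward OR. Toward LC they were Rarres1 (-0.90, SE 0.0789), the NAD synthesis enzyme Qprt (-2.40, SE 0.285, block -2.24), the neuronal tubulin Tubb3 (-2.10), Colec12 (-1.25) and the Fc receptor Fcgr2a (-1.10). None passed (adjusted p from 0.160 to 0.177); limma called 0 genes, and 3236 had an unadjusted p under 0.05. On slides 2 and 3 Gata3 differed by 2.45 and 1.82 and Qprt by -2.38 and -2.40, again in samples from which the genes were picked. The count was 830 without LC normal replicate 1 (613 higher in OR), 3 without LC normal replicate 3, 1 without OP normal replicate 1 and 158 in a fit on all 20 arrays.

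Medians of epithelial and immune lists differed between LC normal tissue and the other 2 groups, and the luminal, myoepithelial and MHC class II lists did not keep their direction on every slide in OP against LC, nor did the luminal list in OR against LC. Luminal genes had a median of 1.20 in OP over LC and 1.09 in OR over LC, myoepithelial genes 0.84 and 0.68, macrophage genes -0.98 and -1.07, proliferation genes -0.81 and -1.07, and MHC class II genes -0.90 and -1.01. Each was among the 9 and 11 lists called with the preset correlation (luminal 2.43e-07 and 1.81e-06), and with an estimated correlation each had adjusted p = 0.600 against OP and 0.671 against OR. Within slides 1, 2 and 3 the OP over LC luminal median was 1.58, -0.13 and 1.55, and the myoepithelial median 1.66, -0.17 and 1.57. The macrophage median was -0.74, -0.76 and -1.17, the proliferation median -0.13, -1.66 and -0.37, and the MHC class II median 0.07, -0.21 and -2.38. On slides 2 and 3 the OR over LC medians were -0.03 and 1.44 for luminal, 0.29 and 0.94 for myoepithelial, -0.78 and -0.92 for macrophage, -1.83 and -1.04 for proliferation, and -0.45 and -2.14 for MHC class II genes. LC normal replicates 1 and 3 had low luminal means (9.52 and 10.04) and myoepithelial means (10.37 and 10.41), while replicate 2 (11.27 and 11.61) lay among the OP and OR tissues. Replicate 3 had the highest MHC class II (13.24) and T and NK cell means (10.83) of the normal tissues. Adjusted over the list alone, 6 of 11 macrophage genes passed in OR against LC, including the complement genes C1qa (-1.78, 0.0344) and C1qc (-1.52, 0.0366), and 2 in OP against LC, Tyrobp (-0.90, 0.0144) and Aif1 (0.0439). Gata3 (1.25, 0.0241), the prolactin receptor Prlr (1.14, 0.0241), Tp63 (1.78), Krt14 (1.63, 0.0432), Wnt4 (1.99, 0.00925) and Sox10 (1.74, 0.00456) passed in OP against LC on the same terms, and over all genes 0 did.

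Obese was set against lean in normal tissue in the same way as in the cancers. Egr1 (0.77), Irf2bpl (0.63), Trib1 (0.88), Pa2g4 (0.39) and Clca5 (1.16) had the smallest p toward OP, and Calm3 (-0.48), Rarres1 (-0.29), Blvra (-0.42), Qdpr (-0.40) and Vhl, a ubiquitin ligase subunit (-0.25, its other probe of opposite sign), in the other direction, each with adjusted p = 1. limma called 0 genes, and 784 had an unadjusted p under 0.05, fewer than the 1802 of chance. This count too rests on the spread shared by all normal tissues, with the more variable LC samples among them. Adiponectin (Adipoq) was at -0.47, Csn2 at 1.22, Erbb2 at 0.26, Esr1 at 0.02, Igf1 at 0.02, Lep at -0.07 and Pgr at 0.10, each with adjusted p = 1. Luminal genes had a median of 0.57 (1.58, -0.09 and 0.96 within slides 1, 2 and 3) and myoepithelial genes of 0.50, with preset adjusted p = 3.93e-05 and 0.000244 and adjusted p = 0.503 each with an estimated correlation; the preset correlation called 10 lists. Adjusted over the list alone Egr1 passed (0.00522).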

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

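The tests on dim probes, on adipocyte markers and on slide 4 were chosen after the result was seen. In each group of 4 to 10 samples, which here means the 6 OP cancers, a sample was looked for whose gap to its nearest neighbour took up more than 0.625 of the whole range. Chance singles out about 1 in 20, and 14 of 149 measures were singled out.

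OP cancer replicate 6 stood apart from the other OP cancers in several measures. These were the T and NK cell list mean (9.38 against 7.70 to 8.18, ratio 0.716), Prf1 (0.716), Sparc (17.06 against 15.34 to 15.82, ratio 0.722), Zcchc9 (10.78 against 11.28 to 11.47, ratio 0.731), Magi3 (0.728) and Tubb3 (9.09 against 7.79 to 8.05, ratio 0.803). It also stood apart in Lep (0.694), near background. OP cancer replicate 1 was low in Tgfa (9.78 against 10.34 to 10.39, ratio 0.923), and replicate 2 had the largest share of probes well above background (79.3% against 61.3% to 67.4%, ratio 0.663). Replicate 3 was low in the cholesterol synthesis list (9.23 against 9.56 to 9.73, ratio 0.657) and high in Pmp22 (0.721). Replicate 4 was high in Csn1s2b (0.745) and Krt15 (0.725).

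Probes that were dim in cancers were brighter in normal tissue. A slide or scan day effect is argued against by slides 1, 2 and 3, where the median minus the 75th percentile was -1.47 in cancers relative to normal tissue, with 4 cancers and an SD of 0.357, against -1.48 over all slides. The negative controls were 0.106 brighter in normal tissue (spread 0.0996), and the dim probes, picked as dim in cancers, differed by 2.67. The controls were read before background correction and the dim probes after it. The 2 values are therefore on different scales and cannot decide on a raised signal on the whole array, which stays open. The amount of RNA, its amplification and a larger range of transcripts in a mixed tissue stay open, and were not tested.

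Adipocyte markers were lower in cancers, with a list mean shifted by -3.75. A lower share of adipocytes alone would raise the markers of all other cells alike. The luminal list mean rose by 2.80 relative to the fibroblast and matrix list mean (spread 0.954). Markers of a list need not be exclusive to its cell type, and whether fat cells share the fibroblast and matrix markers was not tested. The gap therefore cannot decide on this explanation. A higher share of normal epithelium would raise luminal and myoepithelial markers alike, and the luminal mean rose by 1.23 relative to the myoepithelial mean (spread 0.215). The myoepithelial list itself went both ways, with the basal keratin Krt5 up and Oxtr down. Its mean therefore cannot decide on this explanation, which stays open. Other changes in cell composition and changes of expression within cells stay open, and were not tested.

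OP cancers differed from the other cancers in more genes with a small p (4099) than the 1802 of chance. Without slide 4, which held only OP cancers, 7010 genes had an unadjusted p under 0.05, so an excess remained. With scan day as a block as well, 5893 genes did and 593 passed the adjusted threshold. Both fits keep only OP cancer replicates 1 and 2, which were on slides 1 and 2 and scan day 2. Replicate 1 of the OR and of the LC cancers was also read that day. Their replicates 2 and 3 were on slide 5, read on scan day 1. The fits rest on these few arrays, with slide mostly tied to group, and cannot decide on slide or scan day. Of 100 splits of the 12 cancers 3, the real one included, gave as many as the real 4099, the highest other 4229. This share is under 0.05 for a free regrouping of the 12. Several comparisons were tested in this way, another split gave more, and splits that keep slides together were not run, so chance is not excluded. Chance, the slide, shared by no OP and OR cancer, scan day and obesity itself stay open.

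For OP against OR cancers, 8 of 84 splits gave as many genes at an unadjusted p under 0.05 as the real 3926, with 6872 in the highest other, so chance is not excluded. That split set OP cancer replicate 6 with 2 OR cancers of slide 5. For OP against LC cancers 17 of 84 splits reached the real 2599, the highest other 5606, and chance is not excluded. Between OR and LC cancers, 3 of 10 splits reached 1510 (highest other 2448), and 10 splits are too few for a share under 0.05. In normal tissue 4 of 10 splits reached 3177 for OP against LC (highest other 6625), again too few. For obese against lean in normal tissue 71 of 100 splits reached 784 and chance is not excluded. The highest other, 7410, set OP replicate 3 and LC replicates 2 and 3 apart, and the median of the other splits was 1321. As the highest of many splits, 7410 alone cannot show a structure of the samples. For the interaction 33 of 100 splits reached 2534 (highest other 7090), so chance is not excluded. For cancer against normal 1 of 100 splits, the real one, reached 22507 calls (highest other 46), and in OP 1 of 84 reached 16062 (highest other 204), so chance is excluded for both. In LC 1 of 10 splits reached 15701 (highest other 0), too few splits for a share under 0.05.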

How the results depend on the processing

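Tests with scan day, with the arrays of 1 scan day and without slide 4 were chosen after the result was seen. The sign of the named genes held in most alternatives. For cancer against normal, 2535 of 2634 results of named genes kept direction and side of the threshold, 71 fell below it, 20 rose past it and 8 reversed. In OP 334 of 335 held, in OR 336 of 337 and in LC all 336. In the obese against lean comparisons, where none passed, 28 of 576 reversed and 25 rose past the threshold among cancers, and 16 of 353 reversed and 0 rose past it in normal tissue. The cause was not tested except where the construction shows it.

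With 75th-percentile scaling of the processed signal, limma called 12 genes for OP against OR cancers, all lower in OP, and 1 for the interaction, and 24897 for cancer against normal in OP, 23418 in OR and 25199 in LC. After normexp the same scaling called 25688 in OP and 24216 in OR. Quantile normalization of the processed signal called 2 for OP against OR cancers, 1 for OR against LC, 1 for obese against lean and 2 for the interaction. In the authors' table, which holds fewer genes, 12456 were called for cancer against normal, 8753 in OP and 9342 in LC. Requiring a fold of at least 2 left 4185, and 3527 in OP, 4121 in OR and 5068 in LC; the interaction has no such setting, since it has no single fold.

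With slide as a fixed block the counts were 4 for OP against OR cancers, 26 for OP against LC, 1 for OR against LC, 12 for obese against lean and 6 for the interaction, and 19291 for cancer against normal, of which 18349 were shared with the 22507. A fit on all 20 arrays called 2 for OP against LC cancers, 2 for obese against lean, 193 for OP against LC normal tissue and 158 for OR against LC normal tissue. Scan day 1 alone gave 1 for OP against OR cancers, 4 for OP against LC, 1 for OR against LC and 2 for obese against lean. Without slide 4 the counts were 1169 for OP against OR, 1778 for OP against LC and 2313 for obese against lean, where the remaining OP cancers all came from scan day 2. Of 324 pairs of list and comparison, 1 was called with an estimated correlation, 78 with the preset one, 41 by fry, 0 with slide as a block and 3 with 75th-percentile scaling.

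Samples of the same replicate number seldom shared deviations from their group means: of 24 same-number pairs 3 had a correlation over 0.1 (-0.347 to 0.279). Most of these pairs joined different obesity groups, and some means came from only 2 samples. The correlations therefore cannot exclude that a cancer and a normal tissue came from the same rat. With a replicate block limma called 0 genes in each of the obesity comparisons and for the interaction, 21088 for cancer against normal, 11731 in OP, 7024 in OR and 14444 in LC.

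Leaving out 1 sample at a time gave 0 to 45 for OP against OR cancers, 0 to 214 for OP against LC, 0 to 1 for OR against LC, 0 to 516 for obese against lean, 0 to 657 for OP against LC normal tissue, 0 to 830 for OR against LC normal tissue, and 0 for the other 2 normal tissue comparisons. The highest came without OP cancer replicate 6, LC cancer replicate 1 (OR against LC cancers) or LC normal replicate 1. For cancer against normal it gave 20144 to 22900, in OP 10874 to 17440, in OR 3587 to 12375, in LC 12470 to 16330, and for the interaction 0 to 494.

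For cancer against normal, the direction turned under 75th-percentile scaling of the processed signal and after normexp for Esr1 (-1.41 and -0.62), Dio2 (-0.59 and -0.48), Gzmb (-0.19 and -0.16) and Zfp36 (-0.59 and -0.45). These scalings lower most genes in cancers. Slc25a18 in OR against LC cancers turned to -0.0255 after normexp. Calls that ended with slide as a block were Krt15, Prf1, RT1-DOb, Tnnt3 and Tyrobp, and Cdkn2a within OP and Padi3 within OR. Of genes that had not passed for cancer against normal, Cma1 passed with slide as a block (-4.14), with 75th-percentile scaling after normexp (-2.12), on scan day 2 alone (-3.65) and without OP cancer replicate 1 or LC cancer replicate 3. Pvalb passed with 4 other settings, among them both 75th-percentile scalings (-3.81 and -1.44), and without OP cancer replicates 2 or 6, OR normal replicate 1 or LC normal replicate 2. Ptgs2 lost its call with the mean of its probes (adjusted p = 0.378).

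In obese against lean cancers, Esr1 turned to -0.28 and -0.21 under the 75th-percentile scalings, -0.0100 with quantile normalization of the processed signal and -0.00378 with the replicate block. Lep turned to 0.10 with quantile normalization of the processed signal and 0.0288 with slide as a block. Csn2 turned to -7.08 with slide as a block, -0.24 with slide as a random block, -5.28 on scan day 2 alone and -0.39 without slide 4. Igf1 turned to 1.37 with slide as a block, 0.58 on scan day 2 and 0.14 without slide 4. Pgr turned to 0.81 and 0.0617 with slide as a fixed and a random block, 0.0467 with the replicate block, 0.49 on scan day 2 and 0.26 without slide 4. Values with slide as a fixed block rest on 1 OP cancer. Leaving out 1 cancer at a time gave -0.0372 to 0.0696 for Esr1, -0.0273 to 0.00505 for Lep, -0.35 to 2.40 for Csn2 and -0.218 to 0.183 for Pgr. In normal tissue Igf1 turned to -0.0817 and -0.0931 under the 75th-percentile scalings, -0.0749 in the authors' table, -0.0127 with the mean of its probes and -0.0904 with slide as a block. Esr1 turned to -0.0949 with 75th-percentile scaling after normexp. Leaving out 1 normal tissue at a time gave -0.170 to 0.316 for Igf1, -0.0511 to 0.0647 for Esr1, -0.0245 to 0.177 for Pgr, -0.13 to 2.73 for Csn2, and -0.208 to 0.0117 for Lep.

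Of the genes behind counts of 5 or fewer, those with a symbol were Zcchc9, Or2v1 and Qprt. Or2v1, and Qprt in OP against LC normal tissue, were chosen after their values were seen, and the others were without a symbol here. Models with no sample left for a term could not be fitted and have no value, and genes absent from the authors' table have none there.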
